A study of Arabidopsis thaliana with 8 samples.

How the data were processed

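The 8 arrays compared shoots of root-wounded and unwounded Arabidopsis seedlings, 4 arrays at 30 min and 4 at 360 min. Per the labels' protocols, 400 ng of total RNA of each sample was made into Cy3- or Cy5-labelled cRNA, and the dyes were exchanged on the swapped array of each pair as a technical replicate. Groups, replicates and the dye of the wounded RNA were taken from the labels. Each time had its own control RNA.

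Arrays were quantified with Agilent Feature Extraction 7.1.1, per the submitters' processing notes. The deposited scanner files hold, for each of 22575 spots, the mean intensity and the local background intensity in both channels, on a linear scale and without normalization. They also hold a log10 ratio of red (Cy5) over green (Cy3), which per the file headers had the local background subtracted and the dyes normalized. The series matrix holds the authors' log10 ratio for the same arrays. It matched the scanner files' ratio within 0.001 on all 22575 spots of every array, so that its scale and direction are those of that ratio. Its column medians over the probes were 0 on 6 arrays, -0.00183 on 1 and 0.000378 on 1. The ratio was exactly 0 for 212 to 1816 probes per array. No genome build is given in the sources used here, and no coordinates are printed.

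Background was corrected with normexp at an offset of 50 on mean signals and local background medians, and each array was normalized by loess, with 1075 control spots and spots flagged as outliers at weight 0 (limma 3.58.1 in R 4.3.3). The offset pulls the folds of dim genes toward 0. The sign of arrays with the wounded RNA in Cy3 was turned, so that every ratio is wounded over control. Spots marked by Feature Extraction as non-uniform or population outliers, 13 to 888 per array, were left out, and a pair with such a spot gave no value. The 2 arrays of a pair were averaged to 1 replicate. A spot counts as well above background when its corrected signal exceeds a multiple of the background deviation, set to 2.6 per the file headers. Genes were kept if well above background in every channel measurement of at least 1 of the 4 conditions, which left 19178 of 21500. Both times had values for 17444 genes in all 4 replicates, and 33 genes lacked a value at a time. None of the named genes was below background or saturated on every array of a condition, so none is given as a bound. The controls of JAZ5, ORA47 and IAA6 at 30 min were well above background on 1, 2 and 3 of 4 arrays, and folds against such controls are uncertain in size. The 30 min arrays were dimmer than the 360 min arrays, with median red signals of 184 to 271 against 323 to 431. No depth in reads applies to arrays.

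Each of the 21500 probes stands for a different gene by its AGI code, and 98.6% of the codes were found in the annotation table of assembly TAIR10.1, used for symbols alone, while 309 kept their code. A linear model with a coefficient per time was fitted to the 4 replicates with limma's lmFit and eBayes, with 2 residual degrees of freedom and a prior of 3.58. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg at 0.05. The difference between times is the contrast of the coefficients. Because both times share an estimate of the spread, the calls of each time rest partly on the replicates of the other. Of the calls, 11 at 30 min, 44 at 360 min and 72 for the difference rest on a single replicate at a time. Each extraction batch held 1 pair of arrays, so batch and replicate coincide. The p-values rest on the spread between these few replicates, pooled over both times, and more heavily on the prior taken from all genes.

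The 20 gene lists were fixed from the labels and general knowledge (346 genes, of which 338 were on the array and 321 were tested). They were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over lists within each contrast. With an estimated correlation camera uses the 2 residual degrees of freedom, so that test has little power here. The genes named at each time are the 8 highest and 8 lowest log2 folds among genes past the threshold with the same sign on all 4 arrays, up to 3 members with the smallest adjusted p of each list with a member past it, and JAZ10, AOS, LOX2, OPR3, VSP2 and ZAT12 whatever their p. For the difference they are the 5 highest and 5 lowest past the threshold. A gene named by this rule at 360 min is not reported here. A list for genes repressed by sugar, a list for iron deficiency, the expansin and XTH family and a comparison of the unwounded shoots between times were added after the data were seen. For that comparison the average intensities of the arrays were quantile normalized after loess, outlier spots were kept, and the control channel values, averaged over each dye pair, were fitted with lmFit and eBayes.

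The steps were tested on simulated arrays of 19178 genes with changes at 30 min. Of 67 genes changed by a log2 fold of 0.5, 91.0% were recovered, with a median estimate of 0.45. All genes changed by 1 and 2 were recovered, with medians of 0.92 and 1.84. Of 209 calls 15 were false, a share above the nominal 0.05, and 0 of the unchanged genes were called at 360 min. The simulated noise was independent between genes, unlike differences between replicates shared by a whole group of genes. In the simulation a list of 20 genes, all shifted alike, passed in camera and an unshifted list did not. That shift was added after the processing steps and to genes with independent noise, so it says little on the lists tested here.

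Alternatives covered the authors' log ratios, other background and normalization settings, the filter, the dye orientation, the fit, the threshold, a replicate block and leaving out each replicate. Some had a fixed outcome or repeated another, so counts of alternatives passed overstate how far a call holds. Quantile normalizing average intensities leaves the ratios as they are, and an adjusted p under 0.10 can only keep calls. The authors' log ratios were counted from both sources. For the genes of a time, leaving out either replicate of the other time equals fitting that time alone. Chosen after seeing the data were ignoring the outlier flags, keeping genes with no flagged spot, and an offset of 16. Taking the mean over the probes of a gene changes nothing with 1 probe per gene and was not run. A batch block equals the fit with duplicateCorrelation on the replicate. For explanations, a value counted against one when it lay beyond the bound written for it and outside what the explanation needs by more than its SD over replicates or arrays. That condition on the SD was added after the values were seen, for all tests alike, and altered no outcome.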

Results

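Gene expression was measured in shoots of 13-day-old Arabidopsis thaliana Columbia-0 seedlings whose primary root had been wounded with a razor blade 5 mm from the shoot base. The question, as the series title puts it in other words, was which shoot genes respond to a wound made in the root. Shoots were taken 30 or 360 min after wounding, and each RNA was hybridised against RNA of shoots from unwounded seedlings of the same time on 2-colour Agilent arrays. There were 8 arrays in all. At each time there were 2 biological replicates, each measured on 2 arrays with the dyes exchanged, so n = 2 unless a replicate is said to be missing, and the SD is that of 2 replicate means. Of 21500 probes, each for a different gene, the wounded channel was well above background for 72.3% to 88.6% on the 30 min arrays and for 89.6% to 94.9% on the 360 min arrays. A total of 19178 genes were kept. The number of arrays limits the precision of every value.

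At 30 min the 8 highest ratios in wounded over control shoots were those of genes of jasmonate synthesis and signalling and of ERF-1 (AT4G17500). OPR3, which encodes the 12-oxophytodienoate reductase of jasmonate synthesis, rose by a log2 fold of 3.86 ± 0.23 (SD, n = 2), a 14.5-fold change. The transcription factor gene MYC2 rose by 3.62 ± 0.18, and the JAZ repressor genes JAZ9, JAZ1 and JAZ6 rose by 3.75 ± 0.49, 3.46 ± 0.20 and 3.45 ± 0.19. ERF-1, OPCL1 and LOX3 completed the 8 highest, with log2 folds of 3.37 ± 0.32, 3.35 ± 0.03 and 3.27 ± 0.20. The 8 lowest began with AT2G20670, at -2.01 ± 0.03, and AT1G23390, a Kelch repeat F-box gene, at -1.63 ± 0.18. They went on with AT3G59940 at -1.52 ± 0.20, AT1G80440 at -1.50 ± 0.12, AT5G60680 at -1.50 ± 0.33, ATCTH at -1.48 ± 0.39, AT3G15450 at -1.44 ± 0.23 and HBI1 at -1.35 ± 0.13. None of these 8 lowest passed with a trend in the prior. That trend followed the mean log2 ratio of each gene over the replicates and not its intensity. It thus depended on the fold under test and says nothing on brightness. AT2G20670, AT3G15450 and HBI1 also did not pass when either replicate of this time was left out. The 8 highest passed in every alternative that kept the threshold. In all, 867 genes rose and 415 fell at 30 min (limma, Benjamini-Hochberg adjusted p under 0.05), and 154 of the genes that rose and 16 of those that fell changed at least 2-fold. Fitted without replicate 1 or without replicate 2 of this time, the count of 1282 dropped to 304 and 309, and of 56 named genes that passed 31 and 35 still did. With either of those replicates left out, the remaining replicate was assumed to vary like those of the other time.

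Among the lists fixed before the data were examined, jasmonate biosynthesis had 11 of 17 tested members higher at 30 min and none lower (12 adjusted over the list alone). AOS, the allene oxide synthase gene, rose by 1.96 ± 0.05 and LOX2 by 1.53 ± 0.11. Jasmonate signalling had 10 of 15 members higher (12 adjusted over the list alone), among them JAZ5 at 1.49 ± 0.14, with the control well above background on 1 of 4 arrays, and JAZ10 at 1.12 ± 0.21. Of 12 jasmonate defence genes 4 rose (5 adjusted over the list alone), including CLH1 at 2.58 ± 0.01, VSP2 at 1.08 ± 0.12 and CORI3 at 0.80 ± 0.02. ERF and DREB factor genes had 11 of 18 members higher and 2 lower (13 and 2 adjusted over the list alone), with ERF13 at 2.55 ± 0.41, RRTF1 at 1.73 ± 0.04 and ORA47 at 1.22 ± 0.04, its control well above background on 2 of 4 arrays. The size of the folds of such dim genes varied with the processing. It ran from 0.93 without background correction to 3.34 on the authors' log ratios for JAZ5, and from 0.74 to 3.08 for ORA47. The authors' log ratios differ in the dye normalization too, and the cause was not tested. WRKY, ZAT and MYB factor genes had 10 of 16 higher (11 adjusted over the list alone), with WRKY18 at 2.79 ± 0.15, ZAT10 at 2.69 ± 0.12 and WRKY46 at 0.53 ± 0.06, while ZAT12 rose by 0.34 ± 0.01. Calcium and touch genes had 9 of 14 higher (9 adjusted over the list alone). TCH4, a xyloglucan endotransglucosylase gene known for its induction by touch, rose by 2.62 ± 0.11, CML38 by 1.79 ± 0.10 and TCH3 by 1.43 ± 0.01. Glucosinolate and camalexin genes had 8 of 17 higher (8 adjusted over the list alone), with SOT16 at 2.19 ± 0.07, CYP79B3 at 1.28 ± 0.08 and the tryptophan synthesis gene ASA1 at 1.13 ± 0.07.

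Cytokinin response genes had 6 of 16 members lower and 1 higher at 30 min (6 and 1 adjusted over the list alone). The response regulator genes ARR9 and ARR15 fell, with log2 folds of -0.80 ± 0.17 and -0.38 ± 0.07, while CKX4, for a cytokinin oxidase, rose by 0.35 ± 0.08. Auxin response genes went both ways, with 2 higher and 4 lower of 22 (2 and 5 adjusted over the list alone). IAA4 fell, with a log2 fold of -0.87 ± 0.07, whereas IAA5 and IAA6 rose by 0.49 ± 0.10 and 0.81 ± 0.18, the control of IAA6 being well above background on 3 of 4 arrays. Among nitrate genes 1 of 20 rose and 3 fell (1 and 3 adjusted over the list alone), with LBD37 at -0.90 ± 0.10, TGA4 at -0.27 ± 0.03 and HHO2 at 0.46 ± 0.10. In the abscisic acid and dehydration list 6 of 24 rose (6 adjusted over the list alone), among them RD20 at 1.90 ± 0.09, RD26 at 0.75 ± 0.29 and COR15B at 0.50 ± 0.19. The ethylene genes ACS6 and EBF1 rose by 0.77 ± 0.13 and 0.48 ± 0.18, 2 of 13 in that list (3 adjusted over the list alone). PAD4 and EDS1 rose by 0.25 ± 0.05 and 0.23 ± 0.02, 2 of 11 salicylate genes (3 adjusted over the list alone). EDS1 passed in 15 of 24 alternatives and not on the authors' log ratios, and PAD4 passed in 20, with log2 folds from 0.15 to 0.56. RBOHD, for an NADPH oxidase, rose by 0.99 ± 0.27, 1 of 16 oxidative stress genes (1 higher and 2 lower adjusted over the list alone). The anthocyanin regulator gene PAP1 rose by 0.97 ± 0.03, 1 of 17 flavonoid genes (1 adjusted over the list alone). The clock gene ELF3 fell, with a log2 fold of -0.24 ± 0.01, 1 of 16 (2 higher and 2 lower adjusted over the list alone), and the reference gene UBQ10 fell, with a log2 fold of -0.50 ± 0.01, 1 of 14 (1 adjusted over the list alone). On the authors' log ratios the changes of some genes were over 1.5 times as large, with CML38 at 2.86, IAA6 at 1.87, RBOHD at 1.64, PAP1 at 1.60, ACS6 at 1.34, IAA5 at 1.01, WRKY46 at 0.95, CKX4 at 0.78, ARR15 at -0.71, TGA4 at -0.42 and ELF3 at -0.38. Of 12 heat shock, 21 photosynthesis and 10 root marker genes 0 passed in limma's test over all genes, and 0 adjusted over the list alone.

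With camera at a preset correlation of 0.01, 10 of the 20 lists passed at 30 min. Jasmonate biosynthesis had a median log2 fold of 0.50 (adjusted p = 3.22e-17), jasmonate signalling 1.12 (4.64e-16), jasmonate defence 0.18 (0.000805), ERF and DREB factors 0.56 (2.27e-09), WRKY, ZAT and MYB factors 0.37 (2.41e-09), calcium and touch 0.63 (3.64e-07), glucosinolate and camalexin 0.12 (1.92e-07) and salicylate genes 0.07 (0.00932). Cytokinin genes had -0.12 (0.00932) and auxin genes -0.04 (0.0497). Some medians differed in size between replicates 1 and 2, with -0.06 and -0.18 for cytokinin and 0.06 and 0.24 for glucosinolate genes. With an estimated correlation none of these 10 passed, the smallest adjusted p being 0.152. On 2 residual degrees of freedom that test has little power in every contrast, so not passing it decides little. The result for the auxin list held in 10 of 26 alternatives, against 22 for cytokinin and 21 for salicylate genes. Among lists that did not pass, the median, the mean and the direction of the test differed in sign for nitrate, oxidative stress and flavonoid genes.

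**Figure D1:**
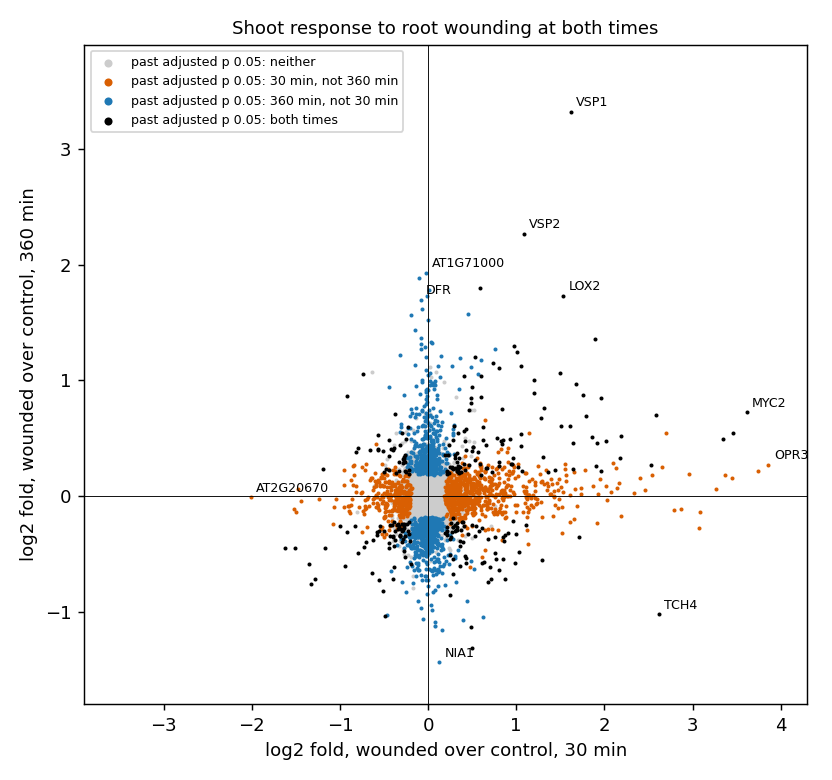
Log2 fold of wounded over control shoots at 30 min (x axis) and at 360 min (y axis), a point per gene, coloured by whether the gene passed an adjusted p of 0.05 in limma. OPR3 (3.86) and MYC2 (3.62) lie far right, VSP1 (3.32) and VSP2 (2.27) high, and TCH4 (2.62 and -1.02) lower right.

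At 360 min the vegetative storage protein genes VSP1 and VSP2 had the highest ratios, with log2 folds of 3.32 ± 0.51 and 2.27 ± 0.21 (SD, n = 2). LOX2 rose by 1.73 ± 0.20 and the anthocyanin synthesis gene DFR 3.24-fold. The 8 highest also held AT1G71000, a DnaJ-type gene, at 1.93 ± 0.25, Hsp70b at 1.88 ± 0.98, AT1G52560, for a chloroplast small heat shock protein, at 1.78 ± 0.73, and HSP22 at 1.72 ± 0.83. The lowest were the nitrate reductase gene NIA1 at -1.44 ± 0.16, PATL2 at -1.31 ± 0.16, EXLA1 at -1.13 ± 0.07 and AT4G16563 at -1.13 ± 0.23. NIA2 followed at -1.09 ± 0.18, FLA9 at -1.07 ± 0.13, GASA1 at -1.06 ± 0.37 and XTH24 at -1.04 ± 0.38. In all, 590 genes rose and 808 fell (limma, Benjamini-Hochberg adjusted p under 0.05), 48 and 12 of them at least 2-fold.

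The count at 360 min depended heavily on the values and on the fit. On the authors' own log ratios it was 130 (74 higher and 56 lower), and with the 360 min arrays fitted alone it was 79 (54 higher and 25 lower). Leaving out either 30 min replicate is the same fit for the 360 min genes and also gave 79. Without 360 min replicate 2 the split turned, with more genes higher than lower. Of 58 named genes that passed at 360 min, 21 passed on the authors' log ratios. VSP1, VSP2, AT1G71000, LOX2, DFR, LDOX, UF3GT, AOS, CORI3, COR15A, COR15B, HSFA2, MAM1, NIA1, NIA2, PATL2, EXLA1, FLA9 and TCH4, 19 genes, passed in every alternative that kept the threshold and gave them a value. Fewer than 50% of the alternatives kept JAZ12, ORA59, ERF105, CML42, TCH2, GH3.5, ARR6, ELF4, PER39 and UBQ10, the fewest being 6 of 23 for GH3.5.

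Heat shock genes had 7 of 12 members higher at 360 min (12 adjusted over the list alone) and a median log2 fold of 0.99. The unwounded shoots of 360 min were themselves far above those of 30 min in these genes, with 11 of 12 higher by a separate limma fit and a median log2 difference of 2.91, so the folds over control sit on a response present in both. HSFA2, for a heat shock transcription factor, rose by 1.33 ± 0.18, HSP101 by 1.06 ± 0.35 and HSP90.1 by 0.57 ± 0.21. The replicates differed in size, with list medians of 1.33 in replicate 1 and 0.51 in replicate 2, and HSP101, HSP90.1, HSP22, Hsp70b and AT1G52560 did not pass on the authors' log ratios. Flavonoid genes had 7 of 17 higher (9 adjusted over the list alone), with LDOX at 1.61 ± 0.09 and UF3GT at 1.43 ± 0.05 beside DFR. Photosynthesis genes had 12 of 21 higher and 1 lower (16 and 2 adjusted over the list alone). The light-harvesting genes LHCB1.1, LHCB1.4 and LHCB4.2 were higher than in control shoots by 0.69 ± 0.18, 0.54 ± 0.05 and 0.44 ± 0.03. From 30 to 360 min LHCB1.1 and LHCB4.2 were lower in unwounded shoots, by log2 differences of -1.45 and -1.53, and the values in wounded shoots were -0.63 and -0.98. In the abscisic acid and dehydration list 6 of 24 rose (11 adjusted over the list alone), with COR15A at 1.04 ± 0.03, COR15B at 0.95 ± 0.01 and KIN2 at 0.84 ± 0.06. The median of that list was 0.55 without replicate 1 and 0.11 without replicate 2.

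Jasmonate defence genes had 6 of 12 members higher and 1 lower at 360 min (6 and 2 adjusted over the list alone), with CORI3 2.15-fold higher. In jasmonate biosynthesis 4 of 16 rose (4 adjusted over the list alone), among them AOS at 0.85 ± 0.07 and OPCL1 at 0.49 ± 0.03, and OPR3 was at 0.27 ± 0.05 (adjusted p = 0.119). In jasmonate signalling 3 of 15 rose (3 adjusted over the list alone), namely MYC2 at 0.72 ± 0.04, JAZ1 at 0.54 ± 0.11 and JAZ12 at 0.33 ± 0.02. JAZ10 was at 0.20 ± 0.44 (adjusted p = 0.531) and ZAT12 at 0.09 ± 0.02 (adjusted p = 0.231). Nitrate genes had 8 of 20 members lower (13 adjusted over the list alone), including UPM1, a sirohaem synthesis gene, at -0.64 ± 0.12. Cytokinin response genes had 4 of 16 lower (8 adjusted over the list alone), among them ARR4 at -0.72 ± 0.26, ARR9 at -0.49 ± 0.22 and ARR6 at -0.26 ± 0.01. Calcium and touch genes had 3 of 14 lower (2 higher and 4 lower adjusted over the list alone). These were TCH4 at -1.02 ± 0.07, CML42 at -0.31 ± 0.17 and TCH2 at -0.25 ± 0.06. Probes of near-identical genes, such as VSP1 and VSP2, the LHCB1 genes and the small heat shock genes, can take up each other's signal.

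Of the other lists, oxidative stress genes had 4 of 16 higher and 1 lower at 360 min (4 and 2 adjusted over the list alone). CAT2, for a catalase, fell, with a log2 fold of -0.44 ± 0.01, while GSTU19 and GSTF6 rose by 0.44 ± 0.21 and 0.38 ± 0.08. Glucosinolate genes had 4 of 17 higher and 1 lower (5 and 5 adjusted over the list alone), with MAM1 at 0.61 ± 0.04, CYP83A1 at 0.29 ± 0.05 and SUR1 at -0.33 ± 0.07. ZAT6 and WRKY33 rose by 0.38 ± 0.05 and 0.47 ± 0.27, 2 of 16 in their list (2 adjusted over the list alone). DREB2A rose by 0.99 ± 0.34 and ORA59 fell, with a log2 fold of -0.27 ± 0.09. ERF105 rose by 0.39 on the evidence of replicate 2 alone, so that the ERF and DREB list had 2 of 18 higher and 1 lower (2 and 2 adjusted over the list alone). GH3.5 rose by 0.21 ± 0.01, 1 of 21 auxin genes (0 adjusted over the list alone). Of the clock genes RVE2 fell, with a log2 fold of -0.45 ± 0.01, and ELF4 rose by 0.19 ± 0.03, out of 16 (2 higher and 2 lower adjusted over the list alone). The root marker PER39 was at -0.38 ± 0.11, the 1 of 10 that fell (1 adjusted over the list alone), and the median of these markers was 0.02. The reference genes UBQ5 and UBQ10 were at -0.27 ± 0.06 and 0.21 ± 0.04, the 2 of 14 that changed (1 higher and 2 lower adjusted over the list alone). Of 11 salicylate genes 0 passed in limma's test over all genes, and 0 adjusted over the list alone.

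With camera at the preset correlation, 10 lists passed at 360 min. The heat shock list (adjusted p = 7.42e-10), nitrate genes (median log2 fold -0.26, adjusted p = 1.26e-08), photosynthesis genes (0.24, 2.60e-08) and the abscisic acid list (0.24, 2.29e-07) had the smallest p. Flavonoid genes followed at 0.23 (4.60e-06), jasmonate biosynthesis at 0.12 (2.05e-05), jasmonate signalling at 0.14 (0.000396), jasmonate defence at 0.14 (0.00436), cytokinin genes at -0.13 (0.0116) and WRKY, ZAT and MYB factors at 0.10 (0.0137). The cytokinin median was -0.06 in replicate 1 and -0.20 in replicate 2. With an estimated correlation none of these 10 passed, the smallest adjusted p being 0.370, and jasmonate signalling did not pass without 360 min replicate 1 (median 0.07, adjusted p = 0.127). Without 360 min replicate 2 the WRKY, ZAT and MYB factors did not pass, and with fry 5 of the 10 did not, namely heat shock, jasmonate signalling, WRKY, ZAT and MYB factors and cytokinin genes (each with an adjusted p of 0.0877) and the abscisic acid list (0.201). The median, the mean and the direction of the test differed in sign for 6 lists that did not pass, those of calcium and touch, auxin, salicylate, glucosinolate, root marker and reference genes.

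**Figure D2:**
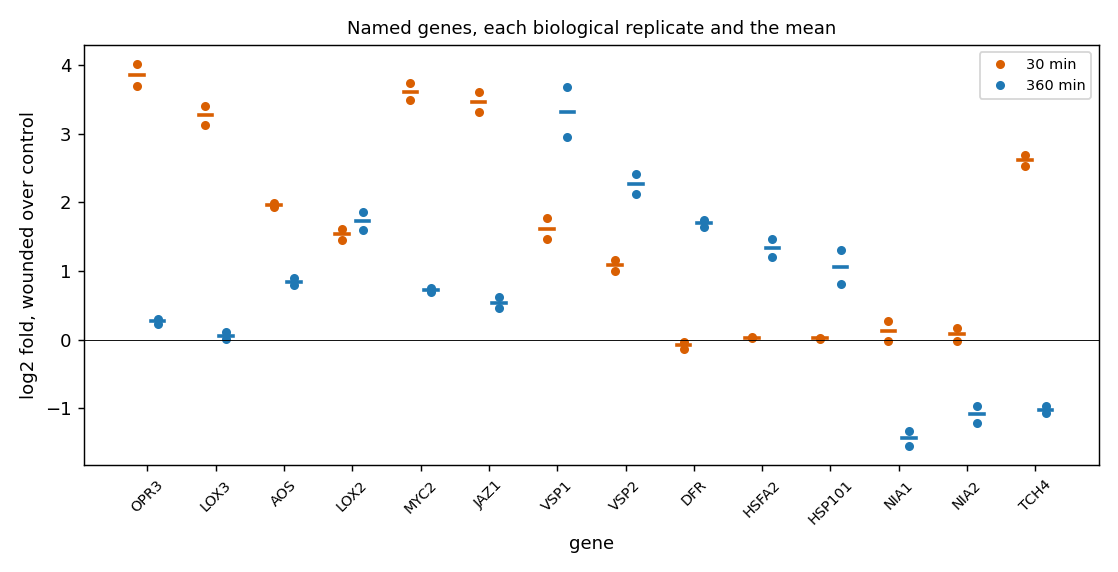
Log2 fold of wounded over control shoots (y axis) for 14 named genes (x axis), with a point for each of 2 biological replicates and a bar for their mean, at 30 min in orange and 360 min in blue. OPR3 lies at 3.86 and 0.27, VSP1 at 3.32 at the later time, and TCH4 at 2.62 and -1.02.

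The response differed between the times for 1414 genes in the contrast of the log2 folds, 490 with a higher and 924 with a lower fold at 360 than at 30 min (limma, Benjamini-Hochberg adjusted p under 0.05). TCH4 had the lowest difference, -3.64 ± 0.08 (SE), followed by OPR3 at -3.59 ± 0.11, JAZ9 at -3.53 ± 0.25, CYP94C1, for a jasmonate-oxidising enzyme, at -3.35 ± 0.34, from replicate 2 alone at 360 min, and JAZ6 at -3.29 ± 0.23. The highest were AT2G20670 at 2.00 ± 0.21, AT1G71000 at 1.95 ± 0.12, AT1G26800 at 1.79 ± 0.07, AT4G14270 at 1.79 ± 0.10 and DFR at 1.78 ± 0.07. On the authors' log ratios 716 genes passed and CYP94C1 did not. AT2G20670 did not pass with the prior's trend over mean log2 ratios, on the arrays with wounded RNA in Cy3, or without either 30 min replicate. AT1G71000 did not pass without 30 min replicate 1, nor JAZ6 without either 30 min replicate. Without 30 min replicate 1 or 2 the counts were 169 and 176.

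By camera the jasmonate signalling list had the smallest adjusted p for the difference, 3.69e-09, with a median of -0.92. The fold over control of the heat shock list was higher at 360 than at 30 min by a median of 0.96 (3.32e-07). Those of photosynthesis and flavonoid genes were higher by 0.27 and 0.26. These are differences of folds and not of levels. From 30 to 360 min the levels of photosynthesis genes had median log2 differences of -0.37 in unwounded and -0.15 in wounded shoots. In all 11 lists passed for the difference, and none of them with an estimated correlation, where the smallest adjusted p was 0.255.

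Genes higher at both times numbered 110, among them VSP2, LOX2, AOS, MYC2 and JAZ1, where 26.7 would be found in independent lists of the same sizes (Fisher's exact test, odds ratio 5.39, Benjamini-Hochberg adjusted p = 1.27e-37). Genes lower at both times numbered 61 against 17.5 (odds ratio 4.15, adjusted p = 2.40e-17). Opposite directions were also more frequent than in independent lists, with 65 genes higher at 30 min and lower at 360 min against 36.5, TCH4 among them, and 37 the other way against 12.8. Genes are not independent of each other, so these p-values are too small. Both times also shared an estimate of the spread of each gene, so that a gene with a small spread is more readily called at both, in any direction. With each time fitted alone, 28 genes were called at both times in the same direction, 26 higher and only 2 lower. Across 17444 genes the log2 folds of the times had a Pearson r of 0.11 and a Spearman rho of -0.000711. The replicates of a time had a Pearson r of 0.87 and a Spearman rho of 0.44 at 30 min, and 0.66 and 0.46 at 360 min. Single arrays at 360 min also differed by dye orientation. The swapped arrays of replicates 1 and 2 had a Pearson r of 0.42 and 0.62. Between the replicates it was 0.71 with the wounded RNA in Cy5 and 0.47 with it in Cy3. On the authors' log ratios 33 genes were called in the same direction at both times, 27 higher and 6 lower. With the prior's trend over mean log2 ratios the number was 76.

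**Figure D3:**
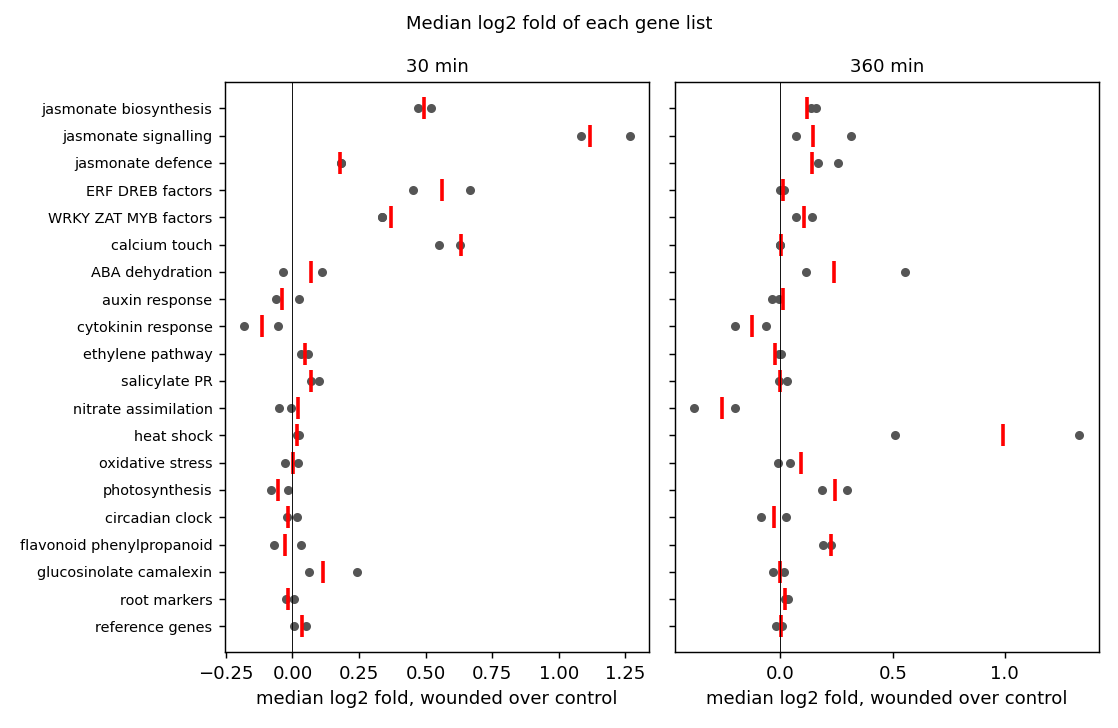
Median log2 fold of wounded over control shoots (x axis) for each of 20 gene lists (y axis) at 30 min (left) and 360 min (right), with a grey point for each replicate and a red mark for the median of the replicate means. Jasmonate signalling lies at 1.12 at 30 min and heat shock at 0.99 at 360 min, with replicate medians of 1.33 and 0.51.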

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

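The tests on the heat shock genes, on root tissue and on array brightness were chosen after their results were seen, and the test of dye bias was set before. The responses of 1414 genes differed between 360 and 30 min by limma's test of the difference. The differences of the named genes were 2.00 for AT2G20670, 1.95 for AT1G71000, 1.79 for AT1G26800, 1.79 for AT4G14270, 1.78 for DFR, -3.64 for TCH4, -3.59 for OPR3, -3.53 for JAZ9, -3.35 for CYP94C1 and -3.29 for JAZ6. By camera with a preset correlation, median differences were -0.33 for jasmonate biosynthesis, -0.92 for jasmonate signalling, -0.46 for ERF and DREB factors, -0.26 for WRKY, ZAT and MYB factors, -0.46 for calcium and touch genes, -0.35 for nitrate genes and -0.0812 for glucosinolate genes. They were 0.22 for the abscisic acid list, 0.96 for heat shock genes, 0.27 for photosynthesis genes and 0.26 for flavonoid genes, and none of the 11 lists passed with an estimated correlation.

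Of 12 heat shock genes 7 were higher in wounded shoots at 360 min, unequally in the replicates, the list not passing in camera with an estimated correlation (adjusted p = 0.412), and in unwounded shoots 11 were already higher at 360 than at 30 min, by a median of 2.91. Signal shared within the small heat shock family would leave other members flat. The median log2 fold of 5 members outside the cytosolic small family was 0.96, with an SD of 0.53 between the replicates. These were HSFA2, HSP101, HSP90.1, HSP70-4 and HSP21, the last of them also a small heat shock gene. HSFA2, HSP101 and HSP90.1 rose by 1.33, 1.06 and 0.57, which argues against shared signal for these genes. HSP70-4 was lower, at 0.46 and 0.17 in replicates 1 and 2. An effect of replicate 1 alone is argued against by a list median of 0.51 in replicate 2. Both replicates, 2 of 2, had medians above 0. What raised these genes in all 360 min shoots was not tested, and whether the wound or a difference in handling or temperature between wounded and unwounded shoots added to it cannot be told apart, since either would coincide with the groups.

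Of 20 nitrate genes 8 and of 16 cytokinin genes 4 were lower at 360 min, and neither list passed in camera with an estimated correlation (adjusted p = 0.370). More root tissue on the unwounded shoots was predicted to lower root markers at least as much as the nitrate genes that fell. The median of the root markers was 0.02, against -0.26 for all 20 nitrate genes. It lay 0.62 above the median of the 8 nitrate genes that fell, a gap partly built in, since these 8 were picked because they fell. The markers as a set were not lowered, though PER39 fell, with a log2 fold of -0.38. The offset pulls folds of dim genes toward 0, so a loss in dim markers is not excluded. The medians of the 8 nitrate genes, -0.74 with the wounded RNA in Cy5 and -0.47 with it in Cy3, decide nothing on dye bias. Such bias cancels by design in the averages of swapped arrays. The cytokinin genes were not tested separately. A response of the shoot to the wound may account for the pattern and was not tested further.

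The log2 folds at 30 and 360 min were nearly uncorrelated across genes. Noise on the dimmer 30 min arrays could hide a shared response, but in the brightest 25% of genes the correlation was 0.13 while the replicates correlated at 0.91 and 0.80. Different genes responding at each time remains a hypothesis, and the controls of the times were separate samples.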

How the results depend on the processing

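The offset of 16 was chosen after seeing the data. On the authors' log ratios, from either source, 130 genes changed at 360 min, 716 differed between times and 33 were called at both times; the cause was not tested. For the remaining normalization settings the cause was likewise not tested. Plain background subtraction gave 843 at 360 min and 108 at both times, an offset of 16 gave 872 at 360 min, scaling between arrays gave 664 and 96, and median centring gave 112 at both times. A trend in the prior over the genes' mean log2 ratios gave 76 at both times. Arrays with wounded RNA in Cy5 gave 2353 at 360 min (880 higher and 1473 lower) and 319 at both times. Those with it in Cy3 gave 779 at 30 min, 190 at 360 min (126 higher and 64 lower), 502 for the difference and 32 at both times. The orientations had equal numbers of arrays, so the number of arrays does not account for the gap between them. Its cause was not tested. All 8 arrays with a dye term gave 2011, 2681, 2713 and 384, with a correlation of 0.0018 within replicates, so that it treats arrays of a pair nearly as independent. Each time fitted alone gave 79 at 360 min and 28 at both times. An adjusted p under 0.10 gave 2282 at 360 min, 2346 for the difference and 291 at both times. A 2-fold minimum on top of the test, which can only remove genes, gave 170, 60, 225 and 8. A 2-fold change on all 4 arrays with no test gave 132 at 30 min, 20 at 360 min and 2 at both times, and the cause was not tested. Leaving out a replicate gave 304 to 1680 genes at 30 min, 79 to 1317 at 360 min, 169 to 1720 for the difference and 14 to 202 at both times. With a replicate block the counts were 1236, 1206, 1272 and 163. Replicate numbers were not taken to pair the times, as the differences between replicates correlated at -0.03. Of 60 tests of lists 31 passed, 29 to 36 under the other settings with camera, 25 with fry and 0 with camera and an estimated correlation. The auxin list at 30 min had a median of -0.0603 without replicate 1 and turned to 0.0227 without replicate 2. No named gene turned its direction while called. Of 56 named calls at 30 min 25 held under every alternative that kept the threshold, of 58 at 360 min 19, and of 10 for the difference 6. As to signal over background, 1355 genes changed at 30 min with all 16 channel measurements well above it and 1250 with no filter.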

Other observations

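The expansin and XTH family and the comparison of unwounded shoots were chosen after results were seen, whereas the tests of the sugar and iron lists were written before the values of their members were seen. The added lists were not run through the alternatives, and of their members only those named by the rule were. Their calls at 360 min come from the joint fit, whose count fell to 79 with that time fitted alone. Genes of cell wall loosening were among the lowest at 360 min. Of 60 tested members 14 were lower and 1 was higher at 360 min (limma, Benjamini-Hochberg adjusted p under 0.05). EXLA1 had a log2 fold of -1.13 ± 0.07 (SD, n = 2), EXGT-A3 of -0.85 ± 0.18, EXPA1 of -0.82 ± 0.11, XTH4 of -0.78 ± 0.17 and XTH16 of -0.59 ± 0.13, while EXPA16 rose by 0.35 ± 0.03. At 30 min EXPA1 was already lower, at -0.52, whereas EXLA1, XTH18 and TCH4 were higher, at 0.48, 0.87 and 2.62. The family was picked because it showed the pattern, so its count is no independent evidence.

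Unwounded shoots of the times were compared through separate channels, from 2 replicates each. A total of 312 genes differed between 360 and 30 min. Heat shock genes were higher at 360 min in 11 of 12 cases, with log2 differences of 6.67 for HSP70-4, 6.50 for HSP90.1, 5.50 for HSP101, 4.98 for HSP17.6C, 4.48 for HSP23.6 and 3.46 for HSFA2. HSP22, at 1.03, did not pass (adjusted p = 0.0533). In wounded shoots the median difference of the list was 4.02. The clock genes LUX, CCR2 and RVE2 were also higher at 360 min, with log2 differences of 1.91, 1.49 and 1.41, and ELF4 passed too. Of 21 photosynthesis genes 0 were higher and 3 lower, with LHCB2.3 at -3.61, and of 24 genes of the abscisic acid list 2 were higher and 4 lower. The times were measured on different arrays, so differences between arrays cannot be told from time in that comparison.

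The ideas behind the sugar and iron lists came from the top genes, which were left off the lists. The hypothesis that genes repressed by sugar fell in wounded shoots at 30 min was not borne out. The median log2 fold of 15 such genes was -0.0918, against the -0.20 required, with an SD of 0.05 between replicates. It was nevertheless below all but 0.01% of 10000 random lists, which ignore correlation between genes, and the adjusted p in camera was 0.0253 with the preset and 0.644 with an estimated correlation. TPS11, TPS8, BGAL4 and AKINBETA1 fell, with log2 folds of -0.68, -0.58, -0.32 and -0.30, and ASN1 rose by 0.27. The bound had been set at a larger shift, and a small shift remains open.

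A hypothesis that the shoot shows an iron deficiency response at 360 min is consistent with a median log2 fold of 0.45 over 9 listed genes, above all of 10000 random lists. At 30 min the median was -0.0937, below all but 0.2% of such lists although 0 of the 9 passed. The replicate medians at 30 min were 0.03 and -0.18, so the sign turned between replicates. The adjusted p in camera with the preset correlation was 0.110 there. At 360 min ZIF1, BHLH101, BHLH39, BTS and OPT3 rose by 0.62 ± 0.12, 0.59 ± 0.20, 0.53 ± 0.22, 0.45 ± 0.21 and 0.39 ± 0.04, and the other 4 did not pass. The replicate medians at 360 min were 0.59 and 0.30, and with camera and an estimated correlation the adjusted p was 0.292. Iron itself was not measured.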
